A study of Homo sapiens with 35 samples.

How the data were processed

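Poly(A)-selected, stranded mRNA libraries of HEK293F cells were sequenced by the authors, and 35 of them are compared here. The cells were given 1 µM HMN-214 or 0.1% DMSO, with no transfection, triple-plasmid transfection or GFP control transfection, and were sampled at 0, 24 and 72 h. The deposited table holds raw read counts per Ensembl gene, one column per library, with no normalization by the authors. Per the submitters' processing notes, HISAT2, Subread and featureCounts were used with GRCh38; their versions, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Every value of the table was checked to be a whole number, and total counts per library ran from 17141771 to 30808293.

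The table holds 60675 genes. Of these, 56558 identifiers were found in the gene-name table, 41209 of them with a gene symbol, and 57055 were found in GENCODE 29, which gave the coordinates. Groups were taken from the labels: 10 groups of 3 libraries at 24 and 72 h, and 2 untransfected libraries at 0 h. The 2 triple-transfection and 1 GFP library at 0 h entered the fit as groups of their own and no comparison. GFP transfection with HMN-214 is not among the 35 libraries and was not analysed here. Counts of the plasmids or of AAV transcripts are not part of the table used here.

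All 35 libraries were fitted together in edgeR 4.0.16 (R 4.3.3) with 1 mean per group, TMM normalization, filterByExpr and the robust quasi-likelihood test; 21425 genes were tested. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in each of 20 comparisons. Interactions are differences of log2 fold changes. CPM are given as mean and SD over libraries. The 28 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at the preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison; a list needed 5 measured members. Counts adjusted over the list alone use the list's genes as the only family. The lists hold genes of G2/M, G1/S, histones, polo-like kinases, p53, interferon, NF-kB, nucleic acid sensing, endoplasmic reticulum chaperones, the integrated stress response, heat shock, immediate early response, YAP/TAZ, cholesterol, glycolysis and hypoxia, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, the mitochondrial genome, tubulins, apoptosis, recombination and Fanconi anaemia, lysosomes, AAV entry, and fibroblast, epithelial, neuronal and blood cell markers.

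Named genes were chosen by a fixed rule. In each of 8 main comparisons it took the 6 higher and 6 lower called genes with the largest log2 change among those with a mean of at least 5 CPM in the higher group, replicates that do not overlap and a proper gene symbol. To these it added a fixed panel of 12 genes and up to 3 called members of each called list in its direction; in the other comparisons it took 3 higher and 3 lower genes. For an interaction the overlap condition was dropped and 5 CPM was needed in 1 of the 4 groups. Further members of the fixed lists are named as examples; they were chosen after their values were seen. Results for a few genes are not reported here. The groups, the comparisons, the tests, the lists, the naming rule and most alternatives were fixed before the data were examined.

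Alternatives were RLE factors, no filter, a stricter filter, a fit of only the groups compared, DESeq2 1.42.0, a replicate block, an estimated correlation and leaving out each library in turn. Chosen after seeing the data were a fit without mitochondrial genes, corrections for gene length and for GC content, and leaving out 3, 4 or 6 libraries that stand apart. The column names give libraries at different times a shared culture code: each replicate has the same code at 24 and 72 h, and 1 of the 2 untransfected libraries at 0 h shares its code with replicate 1 of HMN-214, the other with replicate 1 of DMSO. Whether a shared code means the same flask is not given in the sources used here, and the comparisons over time were made unpaired. The replicate block used the replicate number within a time and the culture code between 24 and 72 h. A culture block for the comparisons with 0 h was added after the data were seen. Deviations of libraries from their group means were summarised by their first axis, which held 10.3% of the variance within groups; its gene loadings had a Spearman correlation of -0.417 with length and 0.455 with GC content over 10883 genes, which are not independent. No pair of libraries was closer than counting error allows, the lowest chi-square per degree of freedom being 2.14.

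The fit was tested on simulated data with 50 genes changed at each of 4 folds. In a comparison like HMN-214 at 24 h, 20, 25, 35 and 43 of 50 were recovered at 1.2-, 1.5-, 2- and 4-fold. In one like triple against GFP transfection at 72 h the numbers were 15, 24, 34 and 40, and for the interaction at 24 h they were 3, 27, 29 and 38. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.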

Results

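Messenger RNA was counted per gene in 35 libraries of HEK293F cells, a human embryonic kidney line adapted to growth in suspension. The cells were given 1 µM HMN-214, a small molecule that the series ties to inhibition of polo-like kinase 1, or 0.1% DMSO. They were left untransfected, transfected with 3 plasmids for the production of adeno-associated virus (AAV), or transfected with a GFP control. The 10 groups at 24 and 72 h held 3 libraries each, and before treatment there were 2 untransfected libraries. A further 2 triple-transfection libraries and 1 GFP library carry the 0 h label and stand in no comparison. Total counts ran from 17141771 to 30808293 per library. Transcripts of the mitochondrial genome took 8.04% ± 0.381 (SD, n = 2) of the counts in untransfected cells at 0 h and between 10.4% and 11.3% (group means) at 24 h. By 72 h the group means lay between 13.6% and 29.1%. Below, log2 fold changes carry their standard error (SE), mean counts scaled to library size (CPM) carry their SD, and n = 3 libraries per group unless stated. Nothing in the labels says that replicates are separate cultures, so the p-values measure the spread between these samples. Higher, lower, rose and fell refer to the other group of a comparison, and not to 0 h unless stated. A call is said to end or be lost under an alternative when its adjusted p is then 0.05 or more, which by itself does not mean that the value shrank.

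**Figure D1:**
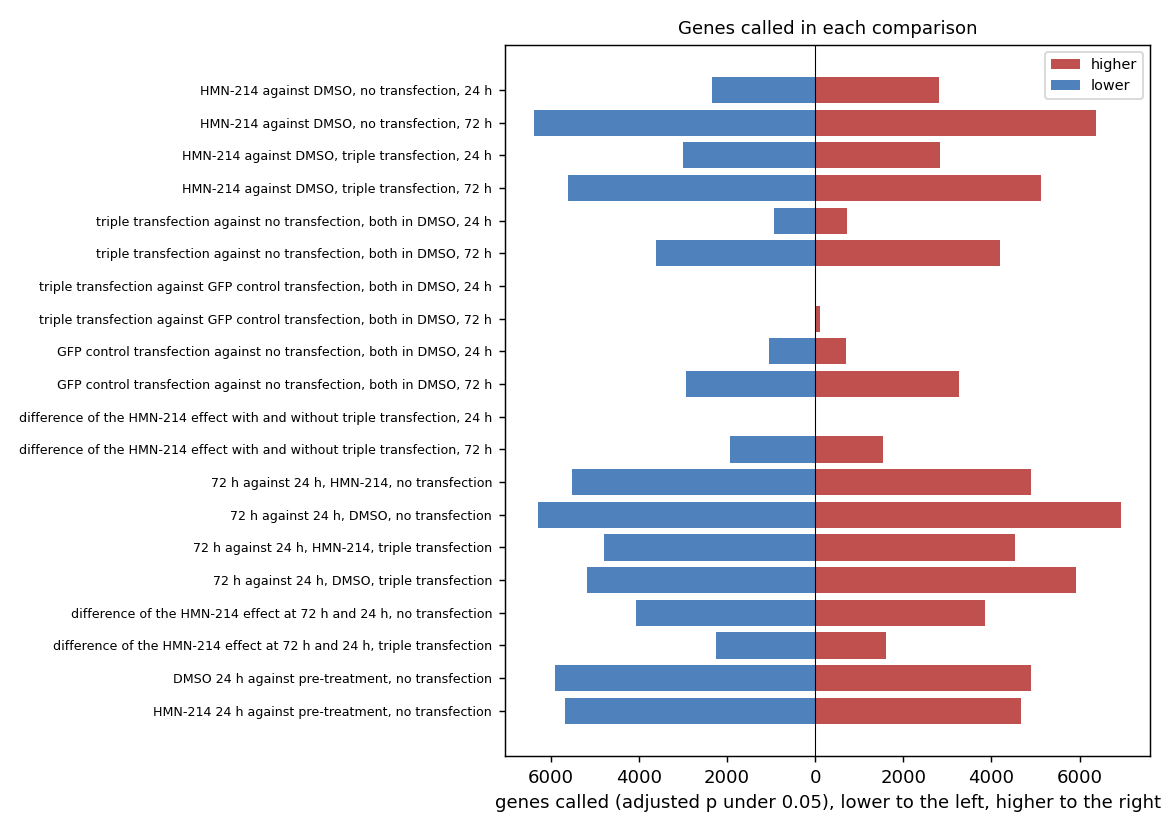
Genes called higher (bars to the right) and lower (bars to the left) in each comparison (vertical axis), as numbers of genes at an adjusted p under 0.05. HMN-214 at 72 h without transfection gave 12751 genes, and triple against GFP transfection at 24 h gave 3.

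The first question was what HMN-214 changes in cells that make no virus. After 24 h, mRNAs of tubulins, the building blocks of microtubules, were lower. TUBB (ENSG00000196230; chromosome 6, 30720201 to 30725426, GRCh38, GENCODE 29 annotation) stood at 1027 ± 41.2 against 2157 ± 51.4 CPM, 2.10-fold lower with HMN-214 (log2 -1.07 ± 0.05, adjusted p = 1.53e-23). TUBB4A fell by 2.09-fold and TUBB4B by 1.94-fold. Among 15 measured tubulin genes, 0 rose (0 adjusted over the list alone), 10 fell (11) and 5 were not called, with a median log2 change of -0.63 (camera adjusted p = 1.55e-13, adjusted p = 0.0157 with an estimated correlation). Because tubulin genes and their pseudogenes are alike in sequence and the handling of reads with several matches is not given in the sources used here, the share of each member is uncertain. Transcripts of mitosis were higher: PLK1 (chromosome 16, 23677656 to 23690367), the kinase named in the series, rose 1.35-fold (log2 0.43 ± 0.05), CDC20, an activator of the anaphase-promoting complex, rose 1.40-fold, and CCNB1, the mitotic cyclin, rose 1.26-fold. In the G2/M list, 32 of 64 rose (37 adjusted over the list alone), 10 fell (11) and 22 were not called, CENPE, KIF4A and DLGAP5 leading (camera adjusted p = 4.15e-06, adjusted p = 0.207 with an estimated correlation).

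Other groups were higher beside them with HMN-214 than in DMSO at 24 h in untransfected cells. Against 0 h (n = 2) this was in part a smaller fall. At 0 h, in DMSO and with HMN-214 the mean log2 CPM was 6.91, 6.61 and 6.83 for ribosome biogenesis genes. It was 3.34, 3.10 and 3.32 for YAP/TAZ targets and 7.02, 6.73 and 6.82 for endoplasmic reticulum chaperones. Heat shock genes had 7.28, 7.55 and 7.88, and immediate early genes 3.61, 3.59 and 3.89. EGR1 (chromosome 5, 138465490 to 138469315), an immediate early transcription factor, went from 6.26 ± 0.105 to 16.9 ± 2.01 CPM (log2 1.43 ± 0.13). Of the 34 immediate early genes, 18 rose (19 adjusted over the list alone), 3 fell (5) and 13 were not called (camera adjusted p = 1.35e-05, adjusted p = 0.144 with an estimated correlation). The constitutive chaperone HSPA8 (chromosome 11, 123057489 to 123063230) was 1.86-fold higher than in DMSO. It stood at 1208 and 1207 CPM in the libraries at 0 h, and at 24 h at 393 to 436 in DMSO and 712 to 805 with HMN-214. Of the 20 heat shock genes, 16 rose (17 adjusted over the list alone), 0 fell (0) and 4 were not called (camera adjusted p = 2.46e-13, adjusted p = 0.115 with an estimated correlation). The nucleolar helicase DDX21 was 1.56-fold higher. Of the 33 ribosome biogenesis genes, 21 rose (22 adjusted over the list alone), 0 fell (0) and 12 were not called (camera adjusted p = 6.83e-12, adjusted p = 0.115 with an estimated correlation). Of the 24 YAP/TAZ targets, 12 rose (13 adjusted over the list alone), 1 fell (1) and 11 were not called, with CCN1 at log2 0.96 ± 0.08 (adjusted p = 0.154 with an estimated correlation). Of the 28 endoplasmic reticulum chaperone genes, 12 rose (14 adjusted over the list alone), 1 fell (3) and 15 were not called, with HSPA5 at log2 0.27 ± 0.04 (adjusted p = 0.318 with an estimated correlation). Both lists were called higher with the preset correlation, the chaperones not with the GC correction (0.0544). Among the 5 polo-like kinase genes 3 rose (3 adjusted over the list alone), 0 fell (0) and 2 were not called (camera adjusted p = 0.0365, adjusted p = 0.133 with an estimated correlation). The call of that list ended without replicate 2 of HMN-214 (0.054) or replicate 3 of DMSO (0.0739), without 3 libraries that stand apart (0.0564) and with only the groups compared (0.054). Of the cholesterol biosynthesis genes, 3 of 27 rose (3 adjusted over the list alone), 12 fell (13) and 12 were not called (adjusted p = 0.284 with an estimated correlation). The largest single decreases by the naming rule were STC1, a secreted glycoprotein (2.50-fold lower), and TSC22D3, a glucocorticoid-induced gene (chromosome X, 107713221 to 107777342; 2.46-fold lower).

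Across all genes, 5149 of 21425 tested were called at 24 h (2816 higher, 2333 lower) and 340 of these changed at least 2-fold. Without the 6 libraries furthest out on the axis of deviations the count was 1873. The tubulin list was the 1 of 28 lists called with both correlations. Nuclear oxidative phosphorylation genes shifted by a median of -0.08: 3 rose (2 adjusted over the list alone), 9 fell (9) and 58 were not called (camera adjusted p = 0.0126, adjusted p = 0.73 with an estimated correlation). That call was lost without replicate 1 (0.269) or 3 (0.234) of HMN-214 or replicate 1 of DMSO (0.265), and with the length correction (median -0.04, 0.511). Not called as lists were interferon-stimulated genes (2 of 40 rose, 3 fell), nucleic acid sensing genes (3 of 16 rose, 2 fell) and apoptosis regulators (6 of 26 rose, 4 fell).

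At 72 h without transfection the largest increases by the naming rule were of ETS transcription factors. ETV5 (ENSG00000244405; chromosome 3, 186046308 to 186110318) and ETV4 (chromosome 17, 43527844 to 43579620), both induced by growth factor signalling, were 11.9-fold higher (11.8 ± 1.87 against 0.989 ± 0.0077 CPM) and 13.2-fold higher, at log2 3.58 ± 0.18 and 3.72 ± 0.22. EGR1 was 5.28-fold higher. The mitotic genes PLK1, CDC20 and CCNB1 stood at log2 0.95 ± 0.05, 0.96 ± 0.06 and 0.75 ± 0.05, while RRM2, a ribonucleotide reductase subunit needed for DNA synthesis, was 2.17-fold lower. The G2/M list as a whole was not called: 28 of 64 rose (28 adjusted over the list alone), 21 fell (22) and 15 were not called, at a median of 0.04 (camera adjusted p = 0.322, adjusted p = 0.764 with an estimated correlation). Nor was the polo-like kinase list (2 of 5 rose, 1 fell; camera adjusted p = 0.259). Of the G1/S genes 13 of 55 rose (13 adjusted over the list alone), 27 fell (27) and 15 were not called (camera adjusted p = 0.016, adjusted p = 0.442 with an estimated correlation). Without replicate 3 of HMN-214 that call ended (adjusted p = 0.056), and so it did with a stricter filter (0.0541) or only the groups compared (0.0835). Genes of homologous recombination and the Fanconi anaemia pathway, which repair breaks and crosslinks in DNA, fell: 6 of 29 rose (7 adjusted over the list alone), 20 fell (20) and 3 were not called (camera adjusted p = 0.00075, adjusted p = 0.333 with an estimated correlation). FANCM was 2.64-fold lower, FANCA (chromosome 16, 89737549 to 89816657) 2.51-fold lower and FANCI 2.40-fold lower. Enzymes of cholesterol synthesis fell as well. HMGCS1 (chromosome 5, 43289395 to 43313512), which makes HMG-CoA, stood at 389 ± 8.09 against 828 ± 49.4 CPM and MVD was 2.58-fold lower. Of the 27 cholesterol genes, 6 rose (6 adjusted over the list alone), 17 fell (17) and 4 were not called (camera adjusted p = 0.00113, adjusted p = 0.333 with an estimated correlation).

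Lysosome and autophagy genes were higher at 72 h in these cells: 23 of 31 rose (23 adjusted over the list alone), 5 fell (5) and 3 were not called (camera adjusted p = 1.27e-05, adjusted p = 0.333 with an estimated correlation). The lysosomal membrane protein LAMP1 was 2.18-fold higher. The mean log2 CPM of the lysosome list was 5.59 at 0 h, and 5.09 in DMSO and 5.51 with HMN-214 at 72 h. Against DMSO, ribosome biogenesis and ribosomal protein genes went opposite ways. Of the 33 biogenesis genes, 24 rose (24 adjusted over the list alone), 3 fell (3) and 6 were not called (DDX21 log2 0.98 ± 0.05; adjusted p = 0.365 with an estimated correlation). Their mean log2 CPM was 6.91 at 0 h, and 6.02 in DMSO and 6.37 with HMN-214 at 72 h. Of the 79 ribosomal protein genes, 4 rose (4 adjusted over the list alone), 57 fell (57) and 18 were not called (RPL14 log2 -0.93 ± 0.06; adjusted p = 0.442 with an estimated correlation). Other short genes fell too: 97 genes under 1 kb outside the ribosomal protein and respiratory chain lists had a median of -0.33. The fall is thus not shown to be particular to ribosomal protein genes. Of the 13 mRNAs of the mitochondrial genome 1 rose (1 adjusted over the list alone), 12 fell (12) and 0 were not called, MT-CO1 at log2 -1.23 ± 0.08 (camera adjusted p = 1.27e-05, adjusted p = 0.442 with an estimated correlation). The mitochondrial share of all counts was 16.3% ± 1.11 with HMN-214 against 29.1% ± 1.86 in DMSO. With a correction for gene length, added after the data were seen, that list's median was -0.52 and its adjusted p = 0.116. Heat shock genes and YAP/TAZ targets were higher as lists with the preset correlation. Of the 20 heat shock genes, 13 rose (13 adjusted over the list alone), 4 fell (4) and 3 were not called, HSPA8 being 2.80-fold higher (adjusted p = 0.442 with an estimated correlation). Of the 24 YAP/TAZ targets, 17 rose (17 adjusted over the list alone), 1 fell (1) and 6 were not called, ANKRD1 being 2.79-fold higher (adjusted p = 0.242 with an estimated correlation). Among neuronal markers 10 rose (10 adjusted over the list alone), 1 fell (1) and 4 were not called, led by the granin CHGA (log2 3.07 ± 0.54; adjusted p = 0.242 with an estimated correlation). CXCL8, an inflammatory chemokine, rose 3.60-fold, whereas its NF-kB list as a whole was not called: 9 rose (9 adjusted over the list alone), 4 fell (4) and 12 were not called (camera adjusted p = 0.157). With the GC correction it was called (median 0.38, adjusted p = 0.029).

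In all, 12751 genes were called at 72 h without transfection (6376 higher, 6375 lower), 3206 of them changed at least 2-fold, and no list kept its call with an estimated correlation, against 10 with the preset one. Among the strongest decreases by the naming rule were FUT3, a fucosyltransferase (7.30-fold lower), and DRD4, a dopamine receptor (7.12-fold lower). Tubulin genes were not called as a list: 5 of 15 rose (6 adjusted over the list alone), 7 fell (7) and 3 were not called (camera adjusted p = 0.226). TUBB itself stood at log2 -0.96 ± 0.05 and TUBA1A at 0.71 ± 0.06.

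**Figure D2:**
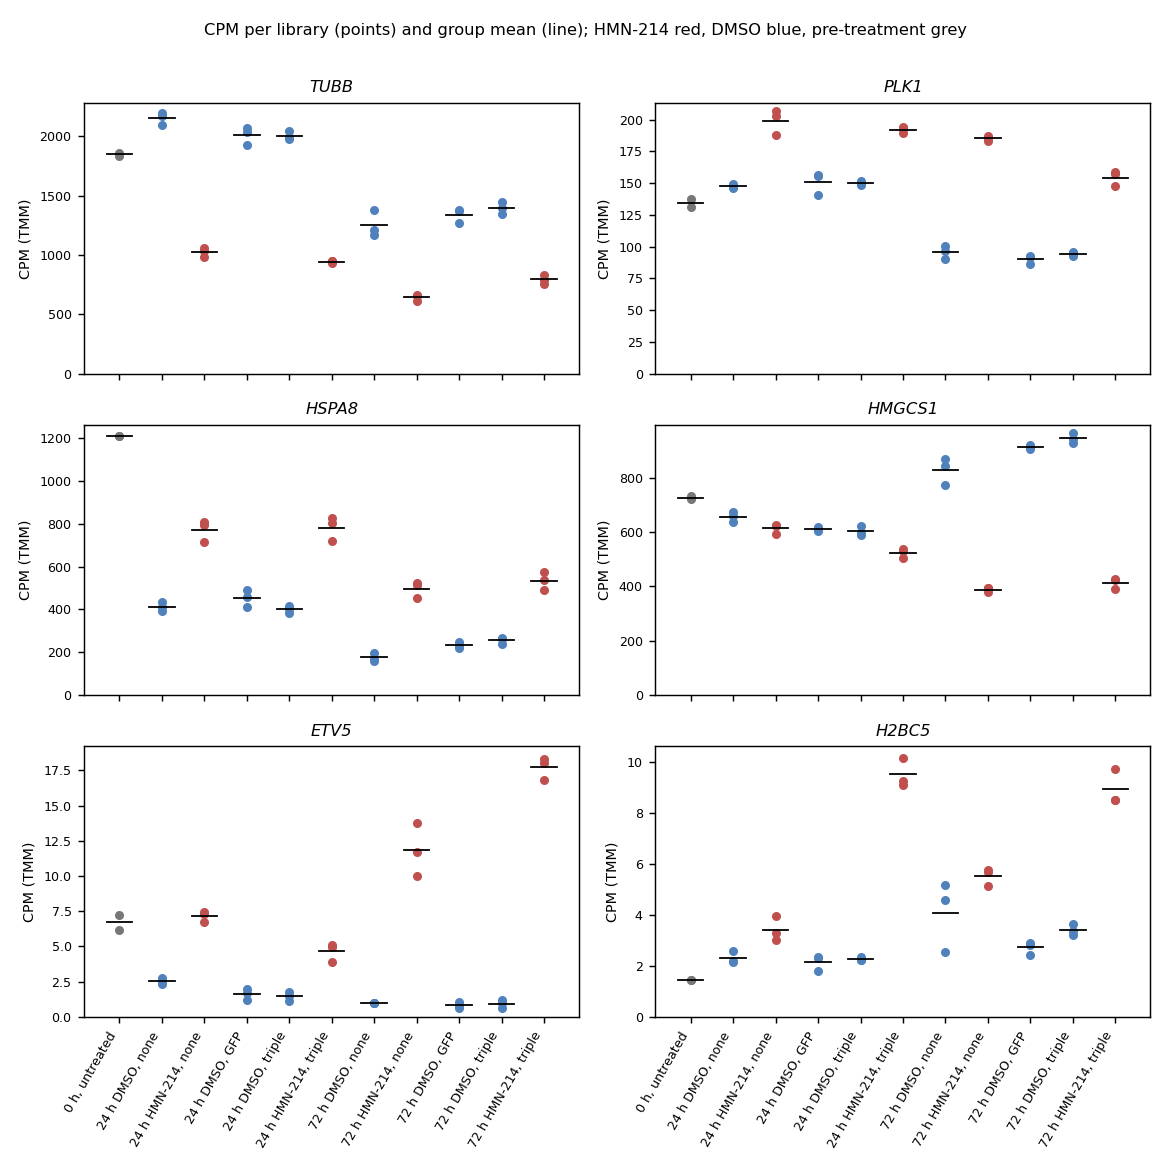
CPM of TUBB, PLK1, HSPA8, HMGCS1, ETV5 and H2BC5 in each library (points) of 11 groups, with the group means; groups run along the horizontal axis. TUBB in untransfected cells at 24 h averaged 1027 CPM with HMN-214 and 2157 in DMSO.

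The second question was what HMN-214 changes during AAV production. At 24 h in triple-transfected cells, TUBB was 2.12-fold lower and TUBB4A 2.44-fold lower. Of the 15 tubulin genes, 0 rose (0 adjusted over the list alone), 12 fell (12) and 3 were not called (camera adjusted p = 2.3e-13, adjusted p = 0.00995 with an estimated correlation). Transcripts of replication-dependent histones, which are mostly made during DNA replication and end without a poly(A) tail, were higher. H2BC5 (ENSG00000158373; chromosome 6, 26158146 to 26171349) stood at 9.50 ± 0.574 against 2.27 ± 0.0795 CPM, 4.17-fold higher (log2 2.06 ± 0.15, adjusted p = 1.76e-16), and H3C6 was 4.37-fold higher. Of the 30 measured of 54 listed histone genes 19 rose (21 adjusted over the list alone), 0 fell (0) and 11 were not called, at a median of 1.25 (camera adjusted p = 1.63e-13, adjusted p = 6.02e-06 with an estimated correlation). The mean log2 CPM of the histone list was -0.32 in DMSO and 0.69 with HMN-214, so the list lay at low levels on average. Histone genes are alike in sequence, which leaves the share of single members uncertain. RRP12 was 1.82-fold higher and DDX21 1.62-fold higher. Of the 33 ribosome biogenesis genes, 25 rose (26 adjusted over the list alone), 0 fell (0) and 8 were not called (camera adjusted p = 6.75e-16, adjusted p = 0.0366 with an estimated correlation).

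PLK1, CDC20 and CCNB1 stood at log2 0.36 ± 0.05, 0.53 ± 0.06 and 0.28 ± 0.05 in that comparison. Of the 64 G2/M genes, 33 rose (34 adjusted over the list alone), 12 fell (14) and 19 were not called (adjusted p = 0.323 with an estimated correlation). Of the 32 targets of the tumour suppressor p53, 3 rose (4 adjusted over the list alone), 15 fell (15) and 14 were not called (adjusted p = 0.288 with an estimated correlation). DDB2 was 1.53-fold lower and BTG2 1.41-fold lower. Of the 32 integrated stress response genes, 15 rose (16 adjusted over the list alone), 6 fell (7) and 11 were not called, ATF3 being 1.68-fold higher (camera adjusted p = 0.0204, adjusted p = 0.393 with an estimated correlation; 0.081 with only the groups compared). Heat shock (13 of 20 rose; HSPA8 1.95-fold higher), immediate early (19 of 34; EGR1 2.33-fold higher), YAP/TAZ (9 of 24) and endoplasmic reticulum chaperone lists (12 of 28) were higher too. They had adjusted p = 0.148, 0.148, 0.148 and 0.354 with an estimated correlation. In turn 17 of 27 cholesterol genes fell (adjusted p = 0.0628 with an estimated correlation). TSC22D3 (3.24-fold lower) and IRS4, an insulin receptor substrate (2.54-fold lower), were among the strongest decreases. The call covered 5831 genes (2835 higher, 2996 lower), 497 of them at least 2-fold. Higher genes were the more common with RLE factors (3095 and 2839 lower), the length and GC corrections and DESeq2. RNU6-510P, a U6 pseudogene, was named by the rule at log2 4.26 ± 1.33, but without replicate 2 of HMN-214 its value was 0.64 (adjusted p = 0.82), and leaving out any DMSO library also ended the call (adjusted p from 0.0591 to 0.0614).

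By 72 h in triple-transfected cells, cholesterol synthesis genes fell together: 2 of 27 rose (2 adjusted over the list alone), 20 fell (20) and 5 were not called, at a median of -0.52 (camera adjusted p = 4.24e-10, adjusted p = 0.0136 with an estimated correlation). HMGCS1 was 2.28-fold lower (log2 -1.19 ± 0.05) and INSIG1, a sterol sensor partner, 2.61-fold lower. Histone mRNAs were higher as well, H3C6 being 4.59-fold higher. Of the 30 histone genes, 21 rose (21 adjusted over the list alone), 0 fell (0) and 9 were not called (camera adjusted p = 3.75e-05, adjusted p = 0.00619 with an estimated correlation). ETV5 and ETV4 were 18.3-fold higher and 14.2-fold higher, and ETV1 was 7.95-fold higher. PLK1 rose 1.63-fold and of the G2/M genes 30 of 64 rose (31 adjusted over the list alone), 16 fell (16) and 18 were not called (adjusted p = 0.526 with an estimated correlation). Of the 28 endoplasmic reticulum chaperone genes, 2 rose (4 adjusted over the list alone), 15 fell (15) and 11 were not called, DERL3 being 2.14-fold lower and HERPUD1 1.67-fold lower (adjusted p = 0.356 with an estimated correlation). Of the 33 ribosome biogenesis genes, 26 rose (28 adjusted over the list alone), 1 fell (1) and 6 were not called (adjusted p = 0.158 with an estimated correlation). Of the 79 ribosomal protein genes, 2 rose (2 adjusted over the list alone), 42 fell (43) and 35 were not called (adjusted p = 0.569 with an estimated correlation). The 97 other genes under 1 kb had a median of -0.16 in this comparison.

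Recombination and Fanconi genes were lower in this comparison as well, EME1 being 2.05-fold lower. Of the 29 recombination and Fanconi genes, 5 rose (5 adjusted over the list alone), 16 fell (16) and 8 were not called (adjusted p = 0.346 with an estimated correlation). Lysosome genes (18 of 31 rose, 6 fell; MCOLN1 1.74-fold higher), stress response genes (17 of 32 rose, 7 fell; SESN2 1.69-fold higher), heat shock genes (12 of 20 rose; HSPA8 2.09-fold higher), immediate early genes (18 of 34) and YAP/TAZ targets (13 of 24) were higher as lists. They had adjusted p = 0.501, 0.483, 0.489, 0.346 and 0.346 with an estimated correlation. Of the 13 mitochondrial mRNAs 11 fell and 1 rose (MT-ND5 log2 -0.76 ± 0.08; adjusted p = 0.498 with an estimated correlation), beside a mitochondrial share of 13.6% ± 0.816 against 18.4% ± 0.647. With the length correction that list's adjusted p was 0.25. The call covered 10729 genes (5131 higher, 5598 lower), with 1923 changed at least 2-fold. Which direction was the more common depended on the scaling: 5846 were higher and 4972 lower with RLE factors, 6133 and 4818 with the length correction, 6071 and 4881 with the GC correction, 5579 and 4779 with DESeq2. Each of the named decreases RNU6-510P and MT-TD came from 1 library, since without DMSO replicate 3 the first stood at -0.66 (adjusted p = 0.764) and without DMSO replicate 1 the second at -0.62 (0.185).

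**Figure D3:**
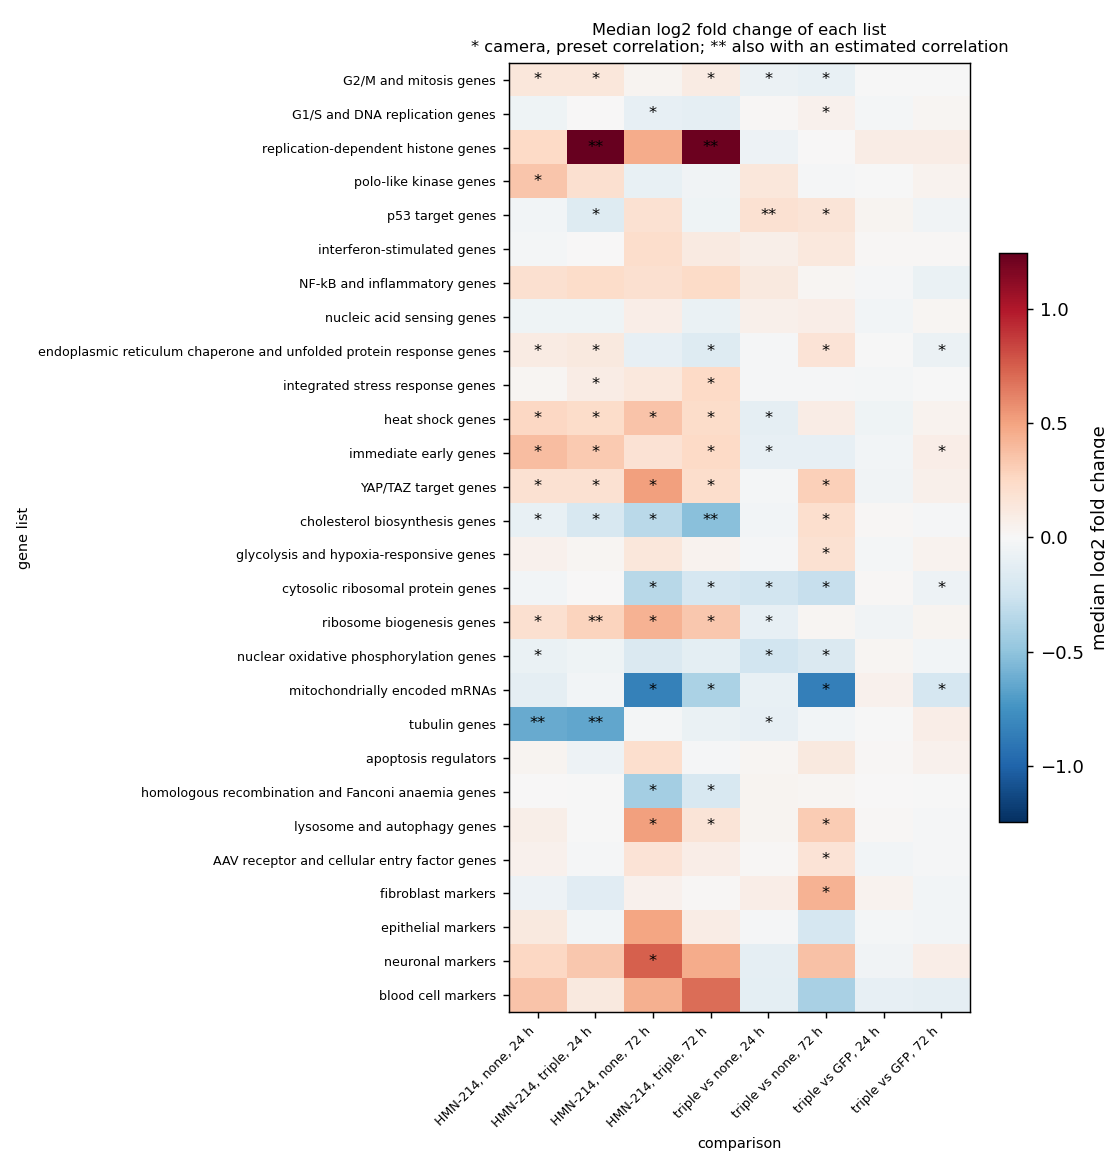
Median log2 fold change of each of the 28 gene lists (vertical axis) in the 8 main comparisons (horizontal axis), red higher and blue lower. One star marks a camera call with the preset correlation and a double star one that also holds with an estimated correlation, as for tubulin genes at 24 h (-0.63 and -0.65).

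The third question was what triple transfection, with AAV production, changes against untransfected cells, both in DMSO. At 24 h, 16 of 32 p53 targets rose (17 adjusted over the list alone), 1 fell (1) and 15 were not called. The list's median was 0.19 (camera adjusted p = 2.03e-12, adjusted p = 0.0105 with an estimated correlation). From 5.50 at 0 h, its mean log2 CPM fell less with triple transfection (5.21) than without (5.02). At 72 h it was 5.27 and 5.10. CDKN1A (ENSG00000124762; chromosome 6, 36676460 to 36687339), the p21 inhibitor of the cell cycle, stood at 146 ± 2.07 against 117 ± 2.91 CPM (log2 0.33 ± 0.06, adjusted p = 0.000471), and the death receptor EDA2R was 1.38-fold higher. INPP5D, an inositol phosphatase, was 1.94-fold higher and CGA, the shared subunit of glycoprotein hormones, 1.94-fold lower. Ribosomal protein mRNAs were lower, in that 0 of 79 rose (0 adjusted over the list alone), 39 fell (62) and 40 were not called (RPL14 log2 -0.33 ± 0.06; camera adjusted p = 1.83e-27, adjusted p = 0.236 with an estimated correlation). Nuclear genes of the respiratory chain were lower in the same way: 1 of 70 rose (1 adjusted over the list alone), 33 fell (54) and 36 were not called (median -0.24; camera adjusted p = 1.83e-20, adjusted p = 0.236 with an estimated correlation). At 24 h, the libraries furthest from their group means on an axis that tracks gene length and GC content were HMN-214 replicate 2 and DMSO replicates 1 and 2 without transfection and DMSO replicate 1 with triple transfection. Ribosomal protein genes share reads with many pseudogenes, so single members are uncertain.

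Further lists were lower at 24 h with the preset correlation. Of the 20 heat shock genes, 0 rose (0 adjusted over the list alone), 6 fell (6) and 14 were not called, HSPA1A being 1.43-fold lower (adjusted p = 0.301 with an estimated correlation). Of the 33 ribosome biogenesis genes, 0 rose (1 adjusted over the list alone), 10 fell (13) and 23 were not called, NPM1 being 1.26-fold lower (adjusted p = 0.258 with an estimated correlation). Of the 64 G2/M genes, 0 rose (0 adjusted over the list alone), 12 fell (18) and 52 were not called, UBE2C being 1.27-fold lower (adjusted p = 0.236 with an estimated correlation). Of the 34 immediate early genes, 0 rose (0 adjusted over the list alone), 4 fell (4) and 30 were not called (adjusted p = 0.342 with an estimated correlation). Of the 15 tubulin genes, 0 rose (0 adjusted over the list alone), 4 fell (5) and 11 were not called (adjusted p = 0.342 with an estimated correlation). The call of immediate early genes ended without DMSO untransfected replicate 1 (0.0705) or triple replicate 2 (0.116), that of tubulin genes without untransfected replicate 3 (0.0925). With the length correction both calls ended (medians -0.05 and -0.08, adjusted p = 0.62 and 0.188), that of immediate early genes also without the 6 libraries furthest out (0.131). The comparison called 1657 genes (714 higher, 943 lower) and 46 at least 2-fold. Without untransfected replicate 3 the number was 812, without triple replicate 2 it was 863, and without 4 libraries at the high end of that axis, a choice made after the data were seen, it was 1004. Without the 6 libraries furthest out at either end it was 538.

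At 72 h in DMSO, LAMP2 was 1.82-fold higher in triple-transfected than in untransfected cells. Of the 31 lysosome genes, 21 rose (23 adjusted over the list alone), 3 fell (3) and 7 were not called (camera adjusted p = 5.11e-09, adjusted p = 0.239 with an estimated correlation). CDKN1A stood at 223 ± 14.5 against 149 ± 9.79 CPM (log2 0.58 ± 0.06) and EDA2R was 1.66-fold higher. Of the 32 p53 targets, 15 rose (15 adjusted over the list alone), 0 fell (0) and 17 were not called (adjusted p = 0.284 with an estimated correlation). LUM, a proteoglycan of the extracellular matrix (chromosome 12, 91102629 to 91111831), was 2.57-fold higher (log2 1.36 ± 0.13), CCN3 2.31-fold higher and the piRNA pathway gene PIWIL2 3.77-fold lower. All 13 mitochondrial mRNAs fell (MT-ND5 log2 -0.95 ± 0.08; camera adjusted p = 3.28e-13, adjusted p = 0.239 with an estimated correlation), beside a mitochondrial share of 18.4% ± 0.647 against 29.1% ± 1.86. With the length correction the median was -0.53 and the adjusted p 0.0524. Other lists were lower. Ribosomal protein genes (48 of 79 fell, 5 rose; adjusted p = 0.393 with an estimated correlation) were among them. So were respiratory chain (33 of 70 fell, 10 rose; adjusted p = 0.535 with an estimated correlation; adjusted p = 0.187 with the length correction) and G2/M genes (29 of 64 fell, 8 rose; HJURP 1.57-fold lower; adjusted p = 0.305 with an estimated correlation). The 97 other genes under 1 kb had a median of -0.47 here. The falls of ribosomal protein and respiratory chain genes are thus not shown to be particular to them. The small RNA gene 7SK and the antisense transcript KCNQ1OT1 stood at log2 -1.61 ± 0.32 and -1.54 ± 0.24; both are uncertain. The first lacks a poly(A) tail, and the second overlaps another gene while the strand setting of the counting is not given in the sources used here.

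Genes tied to AAV uptake by cells were higher as a list at 72 h with triple transfection, such as NDST1 of heparan sulfate synthesis (1.56-fold higher) and TM9SF2 (1.39-fold higher). Of the 17 entry genes, 11 rose (11 adjusted over the list alone), 2 fell (2) and 4 were not called (camera adjusted p = 0.00684, adjusted p = 0.284 with an estimated correlation). With the length correction the entry list was not called (median from 0.17 to 0.13, adjusted p = 0.369). Cholesterol (17 of 27 rose), YAP/TAZ (12 of 24; TGFBR2 1.67-fold higher), glycolysis and hypoxia (17 of 34; SLC2A3 1.66-fold higher) and endoplasmic reticulum genes (15 of 28; OS9 log2 0.59 ± 0.05) were also higher. They had adjusted p = 0.284, 0.284, 0.314 and 0.393 with an estimated correlation. Of these the length correction ended the calls of cholesterol (median from 0.21 to 0.14, 0.0737), glycolysis and hypoxia (median from 0.19 to 0.14, 0.445) and endoplasmic reticulum genes (median from 0.17 to 0.15, 0.168), the last also ended by the GC correction (0.0808) or only the groups compared (0.0537). Of the 9 fibroblast markers, 5 rose (5 adjusted over the list alone), 1 fell (1) and 3 were not called, FBLN1 being at log2 0.58 ± 0.05 (adjusted p = 0.284 with an estimated correlation). Without untransfected replicate 2 that call ended (adjusted p = 0.05), as with the length correction (0.0897). Of the 55 G1/S genes, 18 rose (18 adjusted over the list alone), 4 fell (4) and 33 were not called (adjusted p = 0.535 with an estimated correlation). This call ended without untransfected replicate 1 (0.0881) or 2 (0.102) or triple replicate 1 (0.0943). It also ended with RLE factors (0.0912), a stricter filter (0.159), the length (0.395) or GC correction (0.34), only the groups compared (0.0562), the replicate block (0.0577) and without mitochondrial genes (0.0561). Interferon-stimulated (10 of 40 rose, 5 fell) and nucleic acid sensing genes (3 of 16 rose) were not called as lists (camera adjusted p = 0.307 and 0.332). Epithelial (2 of 11 rose, 4 fell; camera adjusted p = 0.267) and blood cell markers (1 of 6 fell; 0.307) were not called either. Neuronal markers (6 of 15 rose, 0 fell; camera adjusted p = 0.093) were called higher with no filter (0.0182), a stricter filter (0.0437) or the GC correction (0.0332). The comparison called 7794 genes (4194 higher, 3600 lower). The direction that was more common depended on the scaling, with 3803 higher and 3914 lower by RLE factors, 3773 and 3931 by the length correction, 3590 and 4092 by the GC correction. RNU6-510P was again named (log2 4.22 ± 1.41), and without triple replicate 3 it stood at 0.47 (adjusted p = 0.853).

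**Figure D4:**
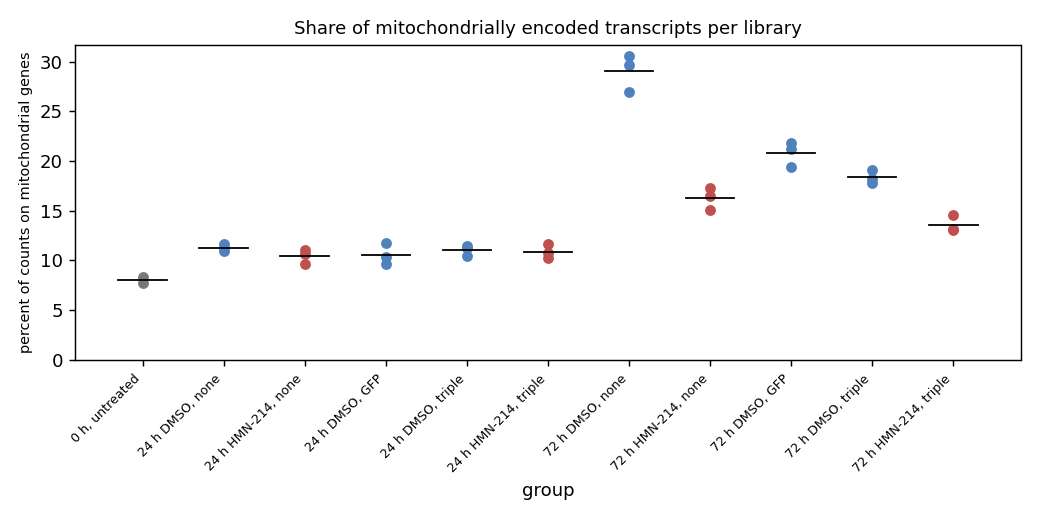
Share of all counts on genes of the mitochondrial genome (percent, vertical axis) in each library (points) by group (horizontal axis), with group means. At 72 h the mean was 29.1% in untransfected DMSO cells and 13.6% in triple-transfected cells given HMN-214.

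Triple transfection was also set against GFP transfection. These arms differ in their plasmids and in GFP, and transcripts of the plasmids were not analysed here. At 24 h, edgeR's quasi-likelihood test called 3 genes. SLC44A2, a choline transporter-like protein (chromosome 19, 10602457 to 10644559), had log2 0.31 ± 0.05 (adjusted p = 0.00107) and CPXM1, a carboxypeptidase-like protein, 0.34 ± 0.07 (0.0373). DNAH17, an axonemal dynein chain (chromosome 17, 78423697 to 78577394), had -0.97 ± 0.14 (0.000351). Of the 21425 tested genes, 1341, the called ones included, had an unadjusted p under 0.05, where 1071 would be expected if no gene differed. DESeq2 called 7. Without triple replicate 1, DNAH17 was the 1 gene left (SLC44A2 adjusted p = 0.0688, CPXM1 0.768), and CPXM1 also lost its call without GFP replicate 1, 2 or 3 (adjusted p from 0.0716 to 0.591) and with the length (0.0557) or GC correction (0.0563). Without the 6 libraries furthest out 0 genes were called. No list was called at 24 h. The heat shock list was called lower with RLE factors (median -0.06, 0.0357) or the length correction (-0.05, 0.0111), and 3 lists were called without triple replicate 2 and 4 without GFP replicate 2. Of the 15140 genes with a mean of at least 1 CPM, 89.54% had a 95% interval of the difference within 1.5-fold.

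At 72 h, 124 genes differed between triple and GFP transfection (114 higher, 10 lower). With the GC correction, added after the data were seen, 30 were called and with the replicate block 71. There were 216 with no filter, 297 with DESeq2 and 545 with only the groups compared. Across genes, which are not independent, the log2 fold changes had a Spearman correlation of -0.446 with GC content. IPMK, an inositol polyphosphate kinase, was 1.41-fold higher (log2 0.50 ± 0.09, adjusted p = 0.0065), LYPLA1, a protein depalmitoylating enzyme, 1.43-fold higher and ADM5 1.62-fold lower. LYPLA1 lost its call without DMSO triple replicate 1, 2 or 3 (adjusted p = 0.059, 0.132, 0.0544) or GFP replicate 2 or 3 (0.141, 0.105) or with the replicate block (0.0556), and ADM5 without triple replicate 2 (0.0655). Mitochondrial mRNAs had a median of -0.21 with 0 of 13 called (camera adjusted p = 1.51e-06, adjusted p = 0.727 with an estimated correlation; 0.535 with the length correction), beside mitochondrial shares of 18.4% ± 0.647 and 20.8% ± 1.27. The other lists called with the preset correlation moved little. Of the 28 endoplasmic reticulum chaperone genes, 0 rose (0 adjusted over the list alone), 1 fell (6) and 27 were not called (median -0.08; adjusted p = 0.605 with an estimated correlation). Of the 34 immediate early genes, 2 rose (6 adjusted over the list alone), 0 fell (0) and 32 were not called (median 0.08; adjusted p = 0.727 with an estimated correlation). Ribosomal protein genes had a median of -0.06 with 0 of 79 called (adjusted p = 0.861 with an estimated correlation), beside -0.095 for 97 other genes under 1 kb. Immediate early genes lost that call without GFP replicate 1 (adjusted p = 0.153), ribosomal protein genes without triple replicate 3 (0.0824) or GFP replicate 3 (0.142). The number of called genes was 35, 7 and 79 without triple replicate 1, 2 and 3, and 42, 15 and 19 without GFP replicate 1, 2 and 3. Of the genes with at least 1 CPM, 89.62% had an interval within 1.5-fold.

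GFP transfection was set against none in DMSO as well. At 24 h, CDKN1A stood at log2 0.38 ± 0.06, DNAH17 was 3.61-fold higher, INPP5D 1.74-fold higher and CGA 2.11-fold lower. Of the 32 p53 targets, 14 rose (17 adjusted over the list alone), 1 fell (1) and 17 were not called (adjusted p = 0.0516 with an estimated correlation). Of the 79 ribosomal protein genes, 0 rose (0 adjusted over the list alone), 48 fell (64) and 31 were not called (adjusted p = 0.216 with an estimated correlation). Of the 70 respiratory chain genes, 1 rose (1 adjusted over the list alone), 41 fell (52) and 28 were not called (adjusted p = 0.179 with an estimated correlation). DMSO replicates 1 and 2 without transfection are among the libraries furthest out on the axis of deviations. At 72 h, LUM was 2.31-fold higher, and lysosome (22 of 31 rose; adjusted p = 0.148 with an estimated correlation) and AAV entry genes (9 of 17; adjusted p = 0.206 with an estimated correlation) were higher as lists. The entry list lost its call with the length correction (median from 0.20 to 0.16, adjusted p = 0.125). The number of called genes was 1750 at 24 h and 6196 at 72 h. At 24 h it was 1011 and 1085 without untransfected replicates 1 and 3, and 853 without GFP replicate 3, and 581 without the 6 libraries furthest out. Of these calls and those of triple transfection, 337 genes were higher and 667 lower in both at 24 h, and 2818 higher and 2468 lower in both at 72 h. In simulations with shared controls and no transfection effect the mean numbers were 0.15 and 0.1 at 24 h and 0.05 and 0.05 at 72 h. Genes were drawn independently there, so hardly any call arises in either comparison. Deviations that many genes of a control library share are also missing. These numbers therefore do not decide how much of the overlap comes from the shared controls. Both comparisons use the same 3 untransfected libraries, so they are not independent, and these libraries were not divided between them.

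Whether triple-transfected cells answer HMN-214 differently was tested as the difference of its effects with and without triple transfection. None of the 35 libraries is from GFP-transfected cells given HMN-214, so this test cannot tell AAV production apart from transfection itself. At 24 h, 7 of 30 histone genes (14 adjusted over the list alone) had a larger effect with triple transfection, 0 a smaller one and 23 were not called, at a median difference of 0.87 (camera adjusted p = 1.59e-25, adjusted p = 1.97e-08 with an estimated correlation). H2BC5 led with a log2 difference of 1.49 ± 0.23 (adjusted p = 6.78e-05). ID3, an inhibitor of differentiation, had a difference of -0.83 ± 0.15. Without the 6 libraries furthest out the differences were 1.51 and -0.71, without a call (adjusted p = 0.0619 and 0.282). In all 17 genes were called (15 with a positive difference, 2 with a negative one). The number was 8 without HMN-214 untransfected replicate 3 or DMSO untransfected replicate 1, 9 without DMSO untransfected replicate 2 or DMSO triple replicate 1 or 3, 10 without HMN-214 triple replicate 3, and 28 without HMN-214 untransfected replicate 2. Without the 6 libraries furthest out it was 9.

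At 72 h the difference reached 3488 genes (1550 positive, 1938 negative). Which sign was the more common depended on the scaling: there were 1865 positive and 1672 negative with RLE factors, and 1937 and 1728 with DESeq2. The length correction gave 2009 and 1729, the GC correction 1930 and 1631. Histone genes again had the larger effect with triple transfection (7 of 30 called, 7 adjusted over the list alone; camera adjusted p = 0.000187, adjusted p = 0.0182 with an estimated correlation). Lysosome genes had the smaller effect (18 of 31 with a negative, 1 with a positive difference). Of 27 cholesterol genes 14 had a negative difference. Both lists had adjusted p = 0.156 with an estimated correlation. CDKN1A differed by -0.41 ± 0.09. PLIN1, which coats lipid droplets, had a difference of 1.84 ± 0.24 and ETS1 one of -1.18 ± 0.28. PLK1 and CCNB1 had smaller effects with triple transfection (differences -0.24 ± 0.07 and -0.27 ± 0.07), PLK1 without a call when the 6 libraries furthest out were left out (adjusted p = 0.0665).

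Time in culture changed much of the transcriptome. In untransfected DMSO cells, FUT3 was 41.1-fold higher at 72 h than at 24 h, while the cell adhesion gene PCDH19 was 8.45-fold lower and AMOT, a regulator of YAP, 5.17-fold lower. GDF15, a stress-induced cytokine, rose 3.29-fold and ATF3 2.59-fold, and PLK1 fell by 1.54-fold. All 13 mitochondrial mRNAs rose (adjusted p = 0.237 with an estimated correlation), beside mitochondrial shares of 11.3% at 24 h and 29.1% at 72 h. With HMN-214, several lists fell with time, and they moved the same way in DMSO. Of the 55 G1/S genes, 1 rose (1 adjusted over the list alone), 49 fell (50) and 5 were not called (camera adjusted p = 9.03e-19, adjusted p = 0.00928 with an estimated correlation). Of the 27 cholesterol genes, 1 rose (1 adjusted over the list alone), 22 fell (22) and 4 were not called (adjusted p = 0.00521 with an estimated correlation). Of the 33 ribosome biogenesis genes, 0 rose (0 adjusted over the list alone), 31 fell (31) and 2 were not called (adjusted p = 0.0255 with an estimated correlation). NF-kB genes and epithelial markers rose. Of the 25 NF-kB genes, 17 rose (17 adjusted over the list alone), 1 fell (1) and 7 were not called, CXCL8 being 3.98-fold higher (adjusted p = 0.00267 with an estimated correlation). Of the 11 epithelial markers, 9 rose (9 adjusted over the list alone), 1 fell (1) and 1 was not called (adjusted p = 0.0452 with an estimated correlation). In DMSO over the same time, 9 of 55 rose and 34 fell (median -0.31, camera adjusted p = 5.39e-05) among G1/S genes, and 4 of 27 rose and 14 fell (median -0.17, camera adjusted p = 0.0346) among cholesterol genes. Of the ribosome biogenesis genes 1 of 33 rose and 30 fell (median -0.63, camera adjusted p = 1.84e-10), a larger median fall than the -0.48 with HMN-214. Of the NF-kB genes 15 of 25 rose and 4 fell (median 0.73, camera adjusted p = 0.0339), and of the epithelial markers 6 of 11 rose and 2 fell (median 0.64, camera adjusted p = 0.11), the last not called. The cholesterol call in DMSO ended with a stricter filter (0.109) or the length correction (0.387). The NF-kB call ended with the GC correction (0.109), with only the groups compared (0.0506) or without DMSO replicate 1 at 72 h (0.0547). With an estimated correlation none of these 5 lists was called in DMSO. With HMN-214, DNAH17 was 8.36-fold higher at the later time. Counts of called genes were 13236 and 10408 in untransfected cells and 11095 and 9322 in triple-transfected cells, for DMSO and HMN-214 in that order.

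The effect of HMN-214 itself differed between 72 and 24 h for 7917 genes without transfection and 3868 with it. Without transfection, ETV4 had a log2 difference of 2.95 ± 0.30 and PLK1 one of 0.52 ± 0.07, whereas HSPA5 had -0.99 ± 0.06. With triple transfection the values were 3.15 ± 0.31 for ETV4 and -0.99 ± 0.07 for HMGCS1. There, 18 of 27 cholesterol genes (19 adjusted over the list alone) had a negative difference, 0 a positive one, and 9 were not called (camera adjusted p = 1.95e-11, adjusted p = 0.0129 with an estimated correlation).

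Against the state before treatment, the heat shock gene HSPA1A was 4.49-fold higher in untransfected DMSO cells at 24 h (1230 ± 19.2 against 274 ± 3.48 CPM, n = 3 and n = 2) and 4.83-fold higher with HMN-214. CDKN1A fell by 2.00-fold and 1.95-fold, CCNE2, a cyclin of DNA replication, by 1.91-fold and 1.73-fold, and INPP5D by 3.59-fold in DMSO. HES7, a segmentation clock repressor, was 7.76-fold higher and CGA 4.80-fold higher in DMSO. Of the p53 targets 2 of 32 rose (2 adjusted over the list alone), 23 fell (23) and 7 were not called in DMSO (adjusted p = 0.128 with an estimated correlation). Respiratory chain genes rose (56 of 70; adjusted p = 0.354 with an estimated correlation), a call that the length correction ended (median 0.29, adjusted p = 0.315). The number of called genes was 10802 for DMSO (4895 higher, 5907 lower) and 10345 for HMN-214 (4672 higher, 5673 lower), with 2 libraries at 0 h. With the GC correction more genes were higher than lower (5616 and 5209 in DMSO, 5462 and 5058 with HMN-214). With a culture block the counts were 8415 and 6726.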

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

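The tests here on gene length, libraries that stand apart and mitochondrial transcripts were chosen only after the result was seen. Lower ribosomal protein and respiratory chain mRNAs in transfected than in untransfected cells at 24 h are the first pattern: the medians were -0.24 and -0.24 with triple transfection and -0.26 and -0.25 with GFP. The mean log2 CPM of ribosomal protein genes went from 8.90 ± 0.09 at 0 h to 9.14 ± 0.12 in untransfected DMSO cells. It was 8.91 with triple and 8.90 with GFP transfection. For respiratory chain genes it went from 5.93 to 6.35, against 6.14 and 6.12. The gap thus went with a larger rise in untransfected cells, not with a fall from 0 h. Short genes were lower in general with triple transfection, and a correction for gene length moved the median of 97 other genes under 1 kb from -0.23 to -0.07. It left the ribosomal protein list at -0.19 (camera adjusted p = 4.8e-15) and the respiratory chain list at -0.16 (1.68e-07). Lengths covered all annotated exons of a gene, which can exceed the mRNA present. Both lists also moved less than the other short genes. The correction therefore cannot decide whether the length trend is the whole cause. Without 4 libraries at the high end of the axis of deviations the medians were -0.22 and -0.23, and without the 6 furthest out at either end, which leaves 1 untransfected DMSO library at 24 h, -0.27 and -0.27. This argues against those libraries as the cause. A response to transfection stays open, untested, and with an estimated correlation neither list was called (adjusted p = 0.236).

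Higher histone mRNAs with HMN-214 in triple-transfected cells at 24 h are the second pattern, found by the test of the difference between the arms: the median difference was 0.87, with 0.48 at 72 h. In untransfected cells at 24 h the list's median was 0.25 (camera adjusted p = 0.0526). It was called higher there under 8 alternatives besides leaving out single libraries, such as the length correction (0.29, 0.00707) and only the groups compared (0.24, 0.0145), so the rise is not shown to be confined to triple-transfected cells. With the length correction the median difference was 0.81, which argues against a length trend. Carry-over of RNA without a poly(A) tail cannot be told apart from a change in histone transcripts. Of 40 listed RNAs of that kind, 7 were measured, with a median difference of 0.30. Its interval of at least 95%, their lowest to highest value, ran from -0.84 to 1.30. That spans the limit of 0.44 set for the test, which therefore decides nothing. A change in the cell cycle, which the title of the series names, stays open: by the same test of the difference the G1/S list had a median of 0.01 (camera adjusted p = 0.107) and the G2/M list one of -0.03 (0.358), neither of them called. The G1/S list was called higher in that test with the length correction (median 0.04, adjusted p = 0.000346), the GC correction (0.04, 0.0069), a stricter filter (0.02, 0.0402) and only the groups compared (0.02, 0.0443).

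The third pattern is the different response to HMN-214 with triple transfection at 72 h, where the test of the difference called 3488 genes. Without mitochondrial genes it called 3489, but leaving them out moved the median of all genes by only -0.0042 in this test, so it decides nothing: the share of mitochondrial transcripts cannot be told apart from another cause. Triple against no transfection differed in 2034 genes within HMN-214 and in 7794 within DMSO, so a smaller transfection effect under the drug is consistent with the pattern at 72 h. This is the same difference seen from the other side, not separate evidence. At 24 h the numbers went the other way, 2213 within HMN-214 and 1657 within DMSO. Of the 25 exchanges of labels within each drug level, 4 gave as many genes, the real one included, and the highest other gave 5383, so chance cannot be excluded by this count. Exchanged labels also move the effect of transfection into the difference, which can raise the other counts.

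Each result here was picked out because a test of the difference between arms or times called it. The difference between the arms at 24 h called 17 genes, and 2 of 25 splits gave as many (highest other 29). HMN-214 by time called 7917 genes without transfection (4 of 25 splits, highest other 11180) and 3868 with it (5 of 25, highest other 9027). Chance cannot be excluded by these counts. Splits that call far more genes than the real one, as with 9027, point to a structure of the samples. Exchanged labels can carry over effects of time (or, between arms, transfection). The other splits can thus hold more than chance, and none of these counts, that of 17 included, settles whether chance gave the result. The median difference of cholesterol genes by time with triple transfection was -0.32.

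Between the arms at 24 h, H2BC5 had a log2 difference of 1.49 and ID3 one of -0.83. H2AC6 stood at 1.16 and DNAH17 at 1.13, and without the 4 libraries at the high end of the axis their adjusted p was 0.155 and 0.251. Without the 6 furthest out at either end the differences were 1.51 for H2BC5, -0.71 for ID3, 1.08 for H2AC6 and 1.17 for DNAH17, none of them called (adjusted p = 0.0619, 0.282, 0.53 and 0.416). At 72 h the differences between the arms were 1.84 for PLIN1, 1.82 for PIWIL2, 1.79 for FUT3, -1.63 for PCDH19, -1.27 for DHRS2 and -1.18 for ETS1. Between the times without transfection they were 2.95 for ETV4, 2.27 for ACTBL2, 2.08 for ETV5, -2.82 for PIWIL2, -2.80 for FUT3 and -2.68 for EZHIP. With triple transfection they were 3.15 for ETV4, 2.53 for ETV5, 2.22 for ACTBL2, -2.03 for FUT3 and -1.62 for ALMS1-IT1. RNU6-510P had -8.67, and without HMN-214 triple replicate 2 at 24 h it had -5.04 (adjusted p = 0.0818), without DMSO triple replicate 3 at 72 h -4.92 (0.0998).

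For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05; in each, 1 of 10 splits gave as many genes, the real one. For HMN-214 the real numbers and the highest others were 5149 and 242 (24 h, no transfection), 12751 and 2 (72 h), 5831 and 1 (24 h, triple transfection) and 10729 and 0 (72 h). For triple against no transfection they were 1657 and 2 at 24 h and 7794 and 29 at 72 h, against GFP 3 and 0, then 124 and 0. For GFP against none they were 1750 and 0, then 6196 and 478. For the comparisons of 72 with 24 h the real numbers were 10408, 13236, 9322 and 11095, and the highest other was 0 in each.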

How the results depend on the processing

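Chosen only after the data were seen were the fit without mitochondrial genes, the length and GC corrections, the culture block and the sets of 3, 4 and 6 libraries left out. Of the counts of called genes under the alternatives, 328 were within 1.5 times the reported count and 37 were not. Among list results 9510 kept direction and side of the threshold, 233 gained and 421 lost a call, and 16 reversed. Of the results for named genes 9837 kept both, 55 gained and 293 lost a call, and 3 reversed. With groups of 3, the simulated interaction at 24 h recovered 3 of 50 genes changed 1.2-fold, so small differences of effect were mostly not detectable. Except where a count rests on fewer libraries or another set of genes, the cause was not tested.

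Triple against no transfection at 24 h called 1004 genes without 4 libraries at the high end of the axis of deviations and 999 without 3 of them; leaving out single libraries gave 812 to 1242. Triple against GFP at 24 h called 9 genes with no filter, 12 with only the groups compared and 7 with DESeq2, and 1 to 4 without single libraries. At 72 h it called 216 with no filter, 30 with the GC correction, 545 with only the groups compared, 297 with DESeq2, and 7 to 79 without single libraries. GFP against none at 24 h gave 853 to 1479 without single libraries. The difference between the arms at 24 h gave 10 genes with only the groups compared and 8 to 28 without single libraries; there, the ribosomal protein median ran from -0.0227 to 0.148. The set of 4 was picked from the high end alone, although other libraries lie as far out at the low end, and 2 of those were added for a set of 6. Without these 6, which leaves DMSO at 24 h and HMN-214 at 72 h with 1 untransfected library each that is assumed to vary like the other groups, HMN-214 at 24 h without transfection called 1873 genes. Triple against none at 24 h then called 538, triple against GFP 0 by edgeR, GFP against none 581, the difference between the arms 9, and HMN-214 by time without transfection 5253.

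Direction reversed with the length correction for mitochondrial mRNAs in triple (0.0522) and GFP (0.0505) against no transfection at 24 h, and for CDC20 (-0.0679), ribosomal protein genes (0.173, by camera's direction), mitochondrial mRNAs (-3e-04), recombination (0.0447) and AAV entry genes (-0.0945, by camera's direction) in DMSO at 24 against 0 h. With HMN-214 against 0 h the same held for histone (0.307), ribosomal protein (0.121) and AAV entry genes (-0.0268), by camera's direction, and for mitochondrial mRNAs (-0.0749). With the GC correction, G2/M (-0.0275) and recombination genes (-0.016) reversed in triple against GFP at 72 h, G2/M genes in 72 against 24 h without transfection (0.0622 with HMN-214, 0.0267 in DMSO), and ATF3 (0.131) and HMGCS1 (0.033) in DMSO at 24 against 0 h. With these scalings the share of higher genes among those called moved by over 10 points for triple against GFP at 24 h, of 3 genes or fewer (from 66.67% to 50% with the length and 33.33% with the GC correction), for HMN-214 by time with triple transfection, from 41.65% to 52.62% with RLE factors, 54.45% with the length and 54.12% with the GC correction, and for 72 against 24 h in untransfected cells given HMN-214 from 47.11% to 58.09% and 59.09% with the length and GC corrections. In the difference between the arms at 72 h, 44.44% of the called genes were positive, and 52.73%, 53.75% and 54.20% with RLE factors, the length and the GC correction. No scaling moved the median of all genes by over 0.1.

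The replicate block was fitted although replicate numbers did not pair the libraries: in no comparison did every same-numbered pair correlate above 0.1. For triple against no transfection at 24 h 1 of the 3 pairs did (0.051 to 0.241). Over time, 1 of the 3 pairs with a shared culture code did, in untransfected cells given HMN-214 (0.148). The block called 4879, 12573, 5586 and 10511 genes for HMN-214 (24 and 72 h without, then with triple transfection), 1402 and 7532 for triple against none, 3 and 71 for triple against GFP, and 1523 and 5945 for GFP against none. The differences between the arms gave 15 and 3213, time gave 10105, 13008, 9041 and 10843, and HMN-214 by time 7634 and 3633. With the culture block, 24 against 0 h called 8415 genes in DMSO and 6726 with HMN-214, each resting on 1 pair of libraries with the same code.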

Other observations

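The list tests in this part were planned, while the length and GC corrections, the axis of deviations and the examples were chosen only after values were seen. In untransfected cells at 72 h, HMN-214 split the interferon-stimulated genes: 17 of 40 rose (17 adjusted over the list alone), 10 fell (10) and 13 were not called (camera adjusted p = 0.242). ISG15, a ubiquitin-like modifier, stood at log2 -1.38 ± 0.09. Apoptosis regulators went both ways as well: 13 of 26 rose (13 adjusted over the list alone), 7 fell (8) and 6 were not called (camera adjusted p = 0.157; 0.03 with no filter). The initiator caspase CASP8 stood at log2 0.99 ± 0.08. Of the glycolysis and hypoxia genes 16 of 34 rose (16 adjusted over the list alone), 7 fell (7) and 11 were not called (0.0831; 0.00714 with no filter, 0.0188 with the GC correction). AAV entry genes were not called as a list with HMN-214 at 72 h, with or without triple transfection. Without transfection they were called higher with no filter (0.0111), the GC correction (0.0483) or without the 6 libraries furthest out (0.0325). Of the 17 entry genes, 10 rose (10 adjusted over the list alone), 4 fell (4) and 3 were not called without transfection (camera adjusted p = 0.109; NDST1 log2 1.08 ± 0.06). With it, 7 of 17 rose (7 adjusted over the list alone), 3 fell (3) and 7 were not called (0.308).

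With time in triple-transfected cells given HMN-214, immediate early and NF-kB genes rose. Of the 34 immediate early genes, 29 rose (29 adjusted over the list alone), 2 fell (2) and 3 were not called (camera adjusted p = 4.72e-13, adjusted p = 0.00942 with an estimated correlation). Of the 25 NF-kB genes, 15 rose (17 adjusted over the list alone), 0 fell (1) and 10 were not called (adjusted p = 0.00302 with an estimated correlation). Other lists fell in those cells. Of the 20 heat shock genes, 1 rose (1 adjusted over the list alone), 18 fell (18) and 1 was not called (adjusted p = 0.0275 with an estimated correlation). Of the 55 G1/S genes, 1 rose (1 adjusted over the list alone), 42 fell (43) and 12 were not called (adjusted p = 0.0202 with an estimated correlation). Of the 27 cholesterol genes, 0 rose (1 adjusted over the list alone), 23 fell (23) and 4 were not called (adjusted p = 0.00302 with an estimated correlation). Of the 33 ribosome biogenesis genes, 0 rose (0 adjusted over the list alone), 31 fell (31) and 2 were not called (adjusted p = 0.0202 with an estimated correlation). In DMSO with triple transfection these lists went the same way, the cholesterol list without a call (0.0412 with no filter). With an estimated correlation 0 of 28 lists were called over time in DMSO, with triple transfection or without. In triple-transfected DMSO cells, 24 of 34 rose and 4 fell (median 0.63, camera adjusted p = 5.29e-07) among immediate early genes, 15 of 25 rose and 3 fell (median 0.77, camera adjusted p = 0.00767) among NF-kB genes, and 3 of 20 rose and 16 fell (median -0.58, camera adjusted p = 4.18e-09) among heat shock genes. For G1/S genes 5 of 55 rose and 35 fell (median -0.23, camera adjusted p = 4.49e-06), for cholesterol genes 9 of 27 rose and 13 fell (median -0.12, camera adjusted p = 0.324) and for ribosome biogenesis genes 0 of 33 rose and 30 fell (median -0.53, camera adjusted p = 4.72e-14). In untransfected cells given HMN-214, histone genes rose with time: 16 of 30 rose (16 adjusted over the list alone), 0 fell (0) and 14 were not called (camera adjusted p = 0.00192, adjusted p = 0.0255 with an estimated correlation). With the length correction that call ended (median 0.58, adjusted p = 0.215), and with the GC correction too (median 0.71, 0.0574). Of the 28 endoplasmic reticulum chaperone genes, 3 rose (3 adjusted over the list alone), 23 fell (24) and 2 were not called (adjusted p = 0.047 with an estimated correlation). Of the 34 glycolysis and hypoxia genes, 2 rose (2 adjusted over the list alone), 24 fell (24) and 8 were not called (adjusted p = 0.0303 with an estimated correlation). In DMSO without transfection, 13 of 30 rose and 0 fell (median 0.52, camera adjusted p = 0.0677) among histone genes. That list was called higher with a stricter filter (0.0223) or without 3 or 4 libraries that stand apart (0.0492, 0.0483). It was also called without DMSO replicate 1 at 24 h (0.0497) or replicate 3 at 72 h (0.0255). Of the chaperone genes 9 of 28 rose and 14 fell (median -0.19, camera adjusted p = 0.283), and of the glycolysis and hypoxia genes 6 of 34 rose and 24 fell (median -0.41, camera adjusted p = 5.28e-05).

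The HMN-214 effects with and without triple transfection shared genes: at 24 h, 1954 were higher and 1744 lower in both and 5 moved opposite ways, where independent calls would give 373, 326 and 702. At 72 h the numbers were 4124, 4516 and 136, against 1527, 1666 and 3193. For triple and GFP transfection against the same untransfected libraries, log2 fold changes across genes correlated at 0.604 at 24 h and 0.743 at 72 h, against 0.516 and 0.534 in 20 simulations with shared controls and no transfection effect. Genes are not independent replicates. The simulations drew them independently, so they leave out deviations that many genes of a control library share.

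The libraries labelled triple transfection at 0 h had a mitochondrial share of 8.79% ± 0.335 (SD, n = 2) and total counts of 27834806 and 17141771. The 1 GFP library at 0 h had 7.67% and 25768567. The ribosomal RNAs of the mitochondrial genome took 6.94% ± 0.654 of the counts in untransfected DMSO cells at 72 h and 2.30% ± 0.159 with HMN-214. On the axis of deviations within groups, where the scores of a group sum to 0, the 4 libraries left out from the high end had scores of 28.6 (DMSO untransfected replicate 1 at 24 h), 23.3 (HMN-214 untransfected replicate 2 at 24 h), 20.9 (DMSO triple replicate 1 at 24 h) and 18.1 (HMN-214 untransfected replicate 2 at 72 h). At the other end stood -21.3 (HMN-214 untransfected replicate 3 at 72 h) and -20.3 (DMSO untransfected replicate 2 at 24 h).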
